A study of Mus musculus with 12 samples.

How the data were processed

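Messenger RNA from ground livers of FVB/N mice was sequenced after mRNA capture with a KAPA kit, per the labels' protocols. Mice had received small interfering RNA (siRNA) in lipid nanoparticles through the tail vein at 0.5 mg/kg, with 1 injection in 5 days, and livers were taken at day 9 or day 13. The siRNA was directed at Eif3m or was a luciferase control. Each of the 4 groups held 3 libraries, 12 in all. The labels call these replicates of livers without stating that each came from a separate animal, so p-values measure the spread between these samples. In the main test that spread was estimated for each gene over both days together, although values varied more among the day 13 libraries of a group.

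The authors deposited a table of estimated counts per Ensembl gene for 50686 genes, with a column for each library. The submitters' processing notes name STAR 2.5.3a, RSEM 1.3.0 and the mouse genome build mm10. The role of each tool, the annotation release, the strand setting and any filter are not given in the sources used here. The values were whole numbers, whereas RSEM gives fractional estimates, so they were taken as rounded expected counts and used as they stood. Gene symbols, positions and exon overlaps came from GENCODE release M21 of the same genome build. Symbols were found for 50376 gene identifiers, and the 310 others held 0.0308% of the counts. A gene and an overlapping or antisense neighbour, or nearly identical copies of a gene, can share such estimated counts, and values for those genes are uncertain.

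Total counts ran from 38783564 to 54538581 in the day 9 libraries and from 7650269 to 9630027 in the day 13 libraries. Genes were kept with the filterByExpr function of edgeR 4.0.16 at a minimum count of 10, which left 14248 genes with at least 99.9% of the counts of every library. Libraries were scaled by the trimmed mean of M-values (TMM), and CPM, the usual unit of counts scaled to library size, were computed from the deposited counts with these factors. The main test was edgeR's quasi-likelihood test, with robust dispersion estimates, on all 12 libraries in a model of 4 groups with 8 residual degrees of freedom. It gave the siRNA effect at day 9, the siRNA effect at day 13 and the day 13 effect minus the day 9 effect, which is called the difference between the days. Tests were two-sided, p-values were adjusted by the method of Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called. Fold changes are on the log2 scale as siRNA over control, with their standard error (SE).

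Before the data were examined, 49 lists of genes of pathways, complexes and cell types were fixed, of whose 1331 members 1263 were tested. Lists were compared with all other genes by camera from limma 3.58.1 with a preset inter-gene correlation of 0.01, and the test was repeated with the correlation estimated for each list. The rotation test fry was run besides, and it asks whether the genes of a list move one way, without comparing them with other genes. For each list the number of called members is given over all genes and adjusted over the list alone. The genes named were set by a rule fixed before the data were examined: Eif3m, the 10 largest rises and the 10 largest falls at each day among called genes with a mean of at least 5 CPM and no overlap between the groups, the 4 members with the smallest p in each called list, up to 2 called members of each other list, and the 5 rises and 5 falls with the smallest p between the days. The rule gave 224 genes, from which examples were taken, and other names are marked where they occur.

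The alternatives were DESeq2 1.42.0 size factors and upper-quartile scaling in the edgeR fit, no filter on low counts, a mean of at least 5 CPM, DESeq2, limma-voom, the replicate number as a block within each day, each day fitted on its own 6 libraries, and leaving out each library in turn. Thinning the day 9 counts to the mean total of the day 13 libraries was added after seeing the data. The steps were tested on simulated data for 14248 genes drawn from the means and library sizes of the real libraries. Among genes changed 1.5-fold, 2-fold and 4-fold, 14.9%, 70.2% and 90.9% were recovered at day 9, 22.4%, 58.2% and 75.8% at day 13, and 1.49%, 20.9% and 77.3% for the difference between the days. False calls made up 5.65%, 3.70% and 4.35% of the calls. The simulation gave each gene the same spread at both days and changed fewer genes than were called in the real data. Its rates may therefore not carry over to these libraries, whose spread differed between the days. No pair of libraries of a group agreed within sampling noise. Analyses used R 4.3.3, and figures used Python 3.11.15 with matplotlib 3.10.9.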

Results

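Liver transcripts were measured in mice given siRNA against Eif3m and in mice given a luciferase control siRNA. Eif3m encodes eIF3m, a subunit of eIF3, the complex that helps bring the small ribosomal subunit to messenger RNA. There were 4 groups of 3 libraries, control and Eif3m siRNA at day 9 and control and Eif3m siRNA at day 13. The day 9 libraries held 38783564 to 54538581 counts and the day 13 libraries 7650269 to 9630027. The library names form a separate set for each day, and the first principal component, with 40.1% of the variance, separated the days. Each siRNA effect was therefore taken within a day, against that day's own controls. The median SD of a gene's log2 CPM within a group was 0.14 and 0.13 in the day 9 control and siRNA groups and 0.27 and 0.25 at day 13. On the third principal component, with 9.44% of the variance, day 13 control replicate 3 lay at −52.0 against 18.0 and 15.3 for the other controls. Day 13 siRNA replicate 2 lay at −36.9 against 37.7 and 4.68 for the other siRNA libraries of that day. Albumin transcripts made up 8.85% ± 0.301 of the counts in the day 9 controls and 7.24% ± 0.176 in the day 9 siRNA group (SD, n = 3). At day 13 they made up 14.6% ± 0.158 in the controls and 9.83% ± 1.73 in the siRNA group (SD, n = 3).

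The targeted transcript was lower in every library of the siRNA groups than in any control library. Eif3m (ENSMUSG00000027170) lies on the minus strand of chromosome 2 from 104999656 to 105017080 of mm10, with 11 merged exons, which overlap exons of Ccdc73. At day 9 its level was 44.8 ± 0.684 CPM in the controls and 4.79 ± 0.0859 CPM in the siRNA livers (SD, n = 3), or 10.7% of the control level. The log2 fold change was −3.23 (SE 0.114, adjusted p = 1.92e-09). At day 13 its level was 36.4 ± 4.56 CPM in the controls and 2.37 ± 0.167 CPM in the siRNA livers (SD, n = 3), or 6.53% of the control level, with a log2 fold change of −3.94 (SE 0.143, adjusted p = 2.66e-09). The counts behind these values were 1753 to 2257 in the day 9 controls, 228 to 287 in the day 9 siRNA libraries, 267 to 296 in the day 13 controls and 18 to 26 in the day 13 siRNA libraries. A two-sided exact permutation test gave p = 0.1 at each day, the smallest value that 3 libraries against 3 allow. The difference of −0.71 between the days did not pass the threshold (adjusted p = 0.0572).

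**Figure D1:**
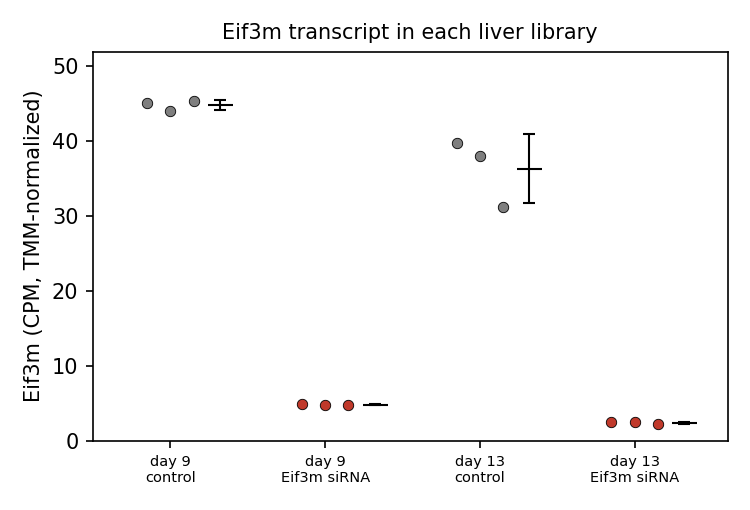
Eif3m transcript in each library, in TMM-normalized CPM (vertical axis), by group (horizontal axis). Points are single libraries (3 per group) and the bars beside them the mean ± SD, and the siRNA libraries lie at 2.19 to 4.88 CPM against 31.2 to 45.4 CPM in the controls.

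The first comparison asked what accompanied the loss of the Eif3m transcript in the liver at day 9. Of 25 p53 target genes, 19 rose and 2 fell, with Cdkn1a, the cell cycle inhibitor p21, going from 0.483 ± 0.115 to 20.8 ± 3.01 CPM (SD, n = 3). Ribosomal protein transcripts rose in 34 of 81 cases and none fell, while 15 of 25 cholesterol synthesis genes fell and none rose. Ifrd1, a transcriptional coregulator, rose from 10.9 ± 0.498 to 68.9 ± 2.18 CPM and Gstt3, a glutathione transferase, fell from 162 ± 15.4 to 26.2 ± 3.78 CPM (SD, n = 3). Among the 14248 genes tested, 846 were higher and 975 lower in the siRNA livers, of which 214 and 205 differed at least 2-fold.

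At day 9, 16 of 47 large-subunit ribosomal proteins rose and none fell (25 adjusted over the list alone), with a median log2 fold change of 0.46. Of 34 small-subunit proteins, 18 rose and none fell (21 adjusted over the list alone), with a median of 0.53. Both lists were called by camera, and their calls were lost with adjusted p = 0.505 and adjusted p = 0.438 with an estimated correlation. Rpl4 went from 420 ± 11.9 to 651 ± 24.6 CPM (SD, n = 3). Of 95 ribosome biogenesis factors, 35 rose and none fell (45 adjusted over the list alone), with a median of 0.33 and adjusted p = 0.0776 with an estimated correlation. These included Rrp12 (log2 fold change 1.28), Nop56 (1.13) and the RNA helicase Ddx21 (0.88). Of 10 genes that host small nucleolar RNAs in their introns, 6 rose (6 adjusted over the list alone), with a median of 1.28 and adjusted p = 0.087 with an estimated correlation. Gas5, one of these hosts, went from 37.1 ± 6.31 to 113 ± 13.0 CPM (SD, n = 3) and Zfas1 rose by 1.77 on the log2 scale. Other eIF3 subunits rose in 4 of 13 cases (6 adjusted over the list alone, median 0.25, adjusted p = 0.364 with an estimated correlation), among them Eif3c at 0.51. Other translation factors rose in 14 of 32 cases (14 adjusted over the list alone, median 0.30, adjusted p = 0.0776 with an estimated correlation), including Pabpc1 and Eif5, both at 0.73. Mitochondrial ribosomal proteins were not called as a list, and 2 of 75 rose and 3 fell (2 and 2 adjusted over the list alone).

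At day 9 the p53 target list had a median log2 fold change of 1.07 (19 up and 2 down, 20 and 3 adjusted over the list alone). Its call held with an estimated correlation (adjusted p = 0.00588). Besides Cdkn1a, with a log2 fold change of 5.44 (SE 0.392, adjusted p = 1.67e-05), Eda2r changed by 4.95, Trp53inp1 by 2.28 and Aen by 1.67. In the integrated stress response, the program that follows phosphorylation of eIF2, 11 of 31 genes rose and 1 fell (16 and 2 adjusted over the list alone, median 0.32, adjusted p = 0.087 with an estimated correlation). Ddit3, which encodes the transcription factor CHOP, went from 5.06 ± 0.730 to 30.8 ± 7.64 CPM, and Atf5 from 291 ± 34.9 to 1160 ± 213 CPM (SD, n = 3). Cytosolic heat shock proteins rose in 6 of 19 cases and fell in 1 (9 and 1 adjusted over the list alone, median 0.23, adjusted p = 0.087 with an estimated correlation), with Hspa8 at 0.71. The unfolded protein response of the endoplasmic reticulum was not called, with 2 of 26 genes up and 2 down (2 and 3 adjusted over the list alone, median 0.02). NRF2 targets were not called either, with 1 of 21 up and 5 down (1 and 5 adjusted over the list alone). The proteasome was not called, with 0 of 31 called by edgeR (0 adjusted over the list alone), 5 by DESeq2, 1 by limma-voom and 9 at an unadjusted p under 0.05. On the day 9 libraries alone edgeR called 9 proteasome genes, all lower.

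The 15 cholesterol synthesis genes that fell at day 9 (18 adjusted over the list alone) included Insig1 (−1.60) and Dhcr7 (−1.31). The list median was −0.88, with adjusted p = 0.364 with an estimated correlation. Of 23 genes of fatty acid and triglyceride synthesis, 9 fell and none rose (15 and 1 adjusted over the list alone, median −0.51, adjusted p = 0.0776 with an estimated correlation). Fasn, the fatty acid synthase, went from 566 ± 184 to 160 ± 12.6 CPM and Pnpla3 from 9.59 ± 5.47 to 0.961 ± 0.505 CPM (SD, n = 3). Conjugating enzymes fell in 19 of 45 cases (29 down and 2 up adjusted over the list alone, median −0.49, adjusted p = 0.0551 with an estimated correlation), among them Gstt3 (log2 fold change −2.62, adjusted p = 2.06e-06). Cytochromes P450 fell in 10 of 41 cases and rose in 3 (13 and 3 adjusted over the list alone, median −0.25, adjusted p = 0.0776 with an estimated correlation), with Cyp2b10, a target of the receptor CAR, at −2.36. Bile acid genes fell in 8 of 23 cases and rose in 1 (10 and 2 adjusted over the list alone, adjusted p = 0.0776 with an estimated correlation), with the bile acid importer Slc10a1 at −0.62. Urea cycle and amino acid catabolism genes fell in 10 of 45 cases and rose in 1 (18 and 2 adjusted over the list alone, median −0.26, adjusted p = 0.427 with an estimated correlation), with Prodh at −1.56 and Ass1 at −0.78. Fatty acid oxidation genes and PPAR alpha targets fell in 8 of 43 cases and rose in 3 (10 and 3 adjusted over the list alone, adjusted p = 0.767 with an estimated correlation), with the hormone gene Fgf21 at 2.71. Nuclear genes of oxidative phosphorylation fell in 2 of 75 cases (1 adjusted over the list alone, 29 on the day 9 libraries alone, median −0.21, adjusted p = 0.767 with an estimated correlation). The share of 2 of 75 was below that of all genes, of which 975 of 14248 were lower. On the day 9 libraries alone the share of 29 was above that of all genes, 1725 of 14817. Pericentral hepatocyte markers fell in 4 of 15 cases (5 adjusted over the list alone, median −0.37, adjusted p = 0.364 with an estimated correlation). Female-biased liver genes fell in 4 of 20 cases (6 adjusted over the list alone, adjusted p = 0.505 with an estimated correlation), with the transporter Slc22a26 at −1.42. Glucose metabolism was not called as a list, with 5 of 30 up and 7 down (5 and 11 adjusted over the list alone), among them G6pc, which releases glucose from glucose 6-phosphate, at 2.37.

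Markers of other cell types moved in both directions at day 9. Of 17 markers of monocytes and infiltrating macrophages, 7 rose and none fell (9 adjusted over the list alone, median 0.70, or 0.42 without siRNA replicate 1, adjusted p = 0.0551 with an estimated correlation). Lyz2, the macrophage lysozyme, went from 42.0 ± 4.50 to 101 ± 7.06 CPM (SD, n = 3), and Ccr2, a receptor of recruited monocytes, rose by 1.24 on the log2 scale. Of 15 markers of Kupffer cells, the resident macrophages of the liver, 5 fell and 1 rose (7 and 2 adjusted over the list alone, adjusted p = 0.505 with an estimated correlation). Clec4f, a Kupffer cell lectin, went from 98.3 ± 7.47 to 24.6 ± 2.48 CPM and Vsig4 from 25.3 ± 3.46 to 7.33 ± 0.512 CPM (SD, n = 3). Inflammatory chemokines and NF-kB targets rose in 3 of 13 cases and fell in 1 (3 and 1 adjusted over the list alone, median 0.56, or 0.18 with a mean of at least 5 CPM and 0.35 without siRNA replicate 1, adjusted p = 0.069 with an estimated correlation), with the adhesion molecule Vcam1 at 1.55. Matrix genes rose in 5 of 26 cases (9 adjusted over the list alone, median 0.38, adjusted p = 0.403 with an estimated correlation), with Lgals3 at 1.43. Cell cycle genes rose in 4 of 31 cases (7 adjusted over the list alone, adjusted p = 0.656 with an estimated correlation), among them Mki67, which went from 1.27 ± 0.362 to 3.93 ± 1.06 CPM (SD, n = 3). The median of this list turned from 0.36 to −0.12 with a mean of at least 5 CPM, where its call ended, and was 0.17 to 0.23 without day 9 control replicate 2 or 3 or siRNA replicate 1. Markers of erythroid cells, neutrophils, T and NK cells, B and plasma cells and cholangiocytes had 0 called members by edgeR and by DESeq2 (0 adjusted over the list alone). At an unadjusted p under 0.05 these lists had 1, 0, 0, 2 and 2 members, and limma-voom called 1 B and plasma cell marker and 1 cholangiocyte marker. On the day 9 libraries alone edgeR called 1 cholangiocyte marker up and 1 down.

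In these tests 1821 genes were called at day 9, with 3902 at an unadjusted p under 0.05, 2581 called by DESeq2 and 2749 by limma-voom. Fitted on the day 9 libraries alone the count was 3412, with 39 of 47 and 30 of 34 ribosomal proteins up, 9 of 13 other eIF3 subunits up and 19 of 45 amino acid catabolism genes down. Without any 1 of the 6 day 9 libraries the count was 884 to 1145. Camera called 24 of the 49 lists, and it also called 14 to 28 lists in the 9 other splits of the 6 libraries, which called at most 1 gene. Each of those splits exchanged 1 siRNA library for 1 control library. They keep part of the siRNA effect and put the rest into the spread within groups. Their counts thus do not show what would be called without an effect. With an estimated correlation camera called 1 list at day 9. Lists are therefore described here by their called members. These are to be read against all 14248 genes, of which the main test called 846 higher and 975 lower at day 9. At day 13 it called 1824 higher and 1553 lower. The called shares of oxidative phosphorylation at day 9 and major urinary proteins at day 13 lay below those of all genes. Those counts from the main test alone show no shift of either list. The call by camera ended for fatty acid oxidation without day 9 control replicate 1 or 2 or siRNA replicate 2 (adjusted p 0.0561 to 0.384), for the cell cycle without control replicate 2 or 3 or siRNA replicate 1 (0.0581 to 0.571), and for female-biased genes without control replicate 3 (0.120).

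The second comparison asked the same at day 13, in a separate set of livers. Ribosomal protein transcripts rose in 70 of 81 cases and none fell, with median log2 fold changes of 1.08 for the large and 1.18 for the small subunit. Trib3, a pseudokinase of the stress response, went from 2.12 ± 0.523 to 74.7 ± 15.6 CPM and Ddit3 from 4.86 ± 1.77 to 87.9 ± 10.5 CPM (SD, n = 3). Of 15 Kupffer cell markers 11 fell, of 40 interferon-stimulated genes 17 fell, and of 20 female-biased liver genes 10 fell and 2 rose. A1bg, a secreted protein with female-biased expression in mouse liver, fell from 748 ± 166 to 14.7 ± 1.59 CPM (SD, n = 3). Among the 14248 genes tested, 1824 were higher and 1553 lower, of which 543 and 496 differed at least 2-fold. Upper-quartile scaling turned the split, with 1574 higher and 1808 lower.

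In the translation machinery at day 13, 41 of 47 large-subunit proteins rose (43 adjusted over the list alone), and 29 of 34 small-subunit proteins rose (29 adjusted over the list alone). For each of these lists adjusted p = 0.124 with an estimated correlation. Rpl4 went from 471 ± 49.1 to 1218 ± 172 CPM and Rplp0 from 451 ± 69.7 to 1232 ± 189 CPM (SD, n = 3). Ribosome biogenesis factors rose in 57 of 95 cases and fell in 1 (68 and 1 adjusted over the list alone, median 0.55), with Npm1, or nucleophosmin, at 1.37. The call held with an estimated correlation (adjusted p = 0.0391). Other translation factors rose in 21 of 32 cases (25 adjusted over the list alone, median 0.52), with Eef1b2 at 1.69. This call also held (adjusted p = 0.0334 with an estimated correlation). Other eIF3 subunits rose in 11 of 13 cases (12 adjusted over the list alone, median 0.67, adjusted p = 0.0628 with an estimated correlation), with Eif3i at 1.06. Hosts of small nucleolar RNAs rose in 6 of 10 cases (8 adjusted over the list alone, median 2.00, adjusted p = 0.0519 with an estimated correlation). Gas5 went from 39.7 ± 12.1 to 305 ± 41.3 CPM (SD, n = 3). Mitochondrial ribosomal proteins rose in 18 of 75 cases and fell in 1 (19 and 1 adjusted over the list alone, adjusted p = 0.713 with an estimated correlation), with Mrps18b at 1.00.

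Stress response genes at day 13 included 16 of 25 p53 targets up and 1 down (16 and 2 adjusted over the list alone, median 1.03), a call that held with an estimated correlation (adjusted p = 0.0334). Cdkn1a rose by 5.07 (SE 0.449, adjusted p = 1.65e-05) and Gdf15, a secreted stress factor, by 3.90 on the log2 scale. In the integrated stress response 15 of 31 genes rose and 3 fell (17 and 4 adjusted over the list alone, median 0.57, adjusted p = 0.087 with an estimated correlation), with Trib3 at 5.16 and Atf5 at 2.73. Cytosolic heat shock proteins rose in 10 of 19 cases and fell in 4 (10 and 5 adjusted over the list alone, median 0.36, adjusted p = 0.306 with an estimated correlation), with Hspb1 at 2.77 and the cochaperone Bag3 at −1.71. The unfolded protein response of the endoplasmic reticulum was not called, with 4 of 26 genes up and 5 down (4 and 6 adjusted over the list alone). Its member Dnajb9 went from 128 ± 18.2 to 39.9 ± 4.19 CPM (SD, n = 3). Immediate early genes rose in 6 of 13 cases (6 adjusted over the list alone, median 0.52, adjusted p = 0.175 with an estimated correlation), with Egr1 at 3.90, whose adjusted p ran from 1.7e-07 to 0.0647 across the alternatives, the last by limma-voom. The largest fitted rise among the named genes was that of Vmn2r3, annotated as a vomeronasal receptor, which had 0 counts in the controls and 659 in the 3 siRNA libraries. This is at least 192-fold higher, against a floor of 3 counts over the control group.

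Metabolic genes that fell at day 13 included 11 of 25 cholesterol synthesis genes (13 adjusted over the list alone, median −0.73, adjusted p = 0.387 with an estimated correlation), with Insig1 at −1.93. Fatty acid and triglyceride synthesis genes fell in 11 of 23 cases and rose in 1 (14 and 1 adjusted over the list alone, median −0.74, adjusted p = 0.087 with an estimated correlation). Fasn went from 678 ± 201 to 130 ± 30.2 CPM (SD, n = 3). Bile acid genes fell in 11 of 23 cases and rose in 1 (11 and 2 adjusted over the list alone, median −0.60). This call held with an estimated correlation (adjusted p = 0.0343). Slc10a1 fell by 1.12 and Cyp27a1, of bile acid synthesis, by 1.04 on the log2 scale. Conjugating enzymes fell in 19 of 45 cases and rose in 6 (22 and 6 adjusted over the list alone, median −0.42, adjusted p = 0.107 with an estimated correlation), with Gstt3 at −2.76. Fatty acid oxidation genes and PPAR alpha targets fell in 12 of 43 cases and rose in 4 (12 and 5 adjusted over the list alone, adjusted p = 0.713 with an estimated correlation), with Hadh at −1.23. Pericentral hepatocyte markers fell in 7 of 15 cases (10 adjusted over the list alone, median −0.57, adjusted p = 0.168 with an estimated correlation), with Glul at −0.73. Female-biased genes had a median of −0.69 (11 down and 3 up adjusted over the list alone, adjusted p = 0.126 with an estimated correlation), with Slc22a26 at −3.29 and the flavin monooxygenase Fmo2 at −2.06. Male-biased genes rose in 3 of 15 cases (4 adjusted over the list alone, adjusted p = 0.306 with an estimated correlation), with the steroid enzyme Hsd3b5 at 2.43. Major urinary proteins rose in 2 of 19 cases (2 adjusted over the list alone, adjusted p = 0.634 with an estimated correlation), with Mup21 at 4.40. The share of 2 of 19 was below that of all genes, of which 1824 of 14248 were higher. On the day 13 libraries alone 3 of 18 rose, a share above that of all genes, 1060 of 11964. Cytochromes P450 were not called, with 8 of 41 up and 13 down (9 and 15 adjusted over the list alone), nor were urea cycle and amino acid catabolism genes, with 8 of 45 up and 8 down (9 and 8 adjusted over the list alone).

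The 11 Kupffer cell markers that fell at day 13 (12 down and 1 up adjusted over the list alone, list median −0.95, adjusted p = 0.168 with an estimated correlation) included Csf1r, C1qa and Clec4f, the last going from 93.0 ± 24.1 to 28.8 ± 12.8 CPM (SD, n = 3). Erythroid markers fell in 5 of 7 cases (7 adjusted over the list alone, adjusted p = 0.357 with an estimated correlation). Interferon-stimulated genes had a median of −0.61 (17 down adjusted over the list alone, adjusted p = 0.168 with an estimated correlation), with Iigp1 at −1.67 and Usp18 at −1.74. Acute phase genes fell in 13 of 30 cases and rose in 3 (18 and 3 adjusted over the list alone, median −0.39, adjusted p = 0.168 with an estimated correlation), with Lcn2 at −3.49, Orm2 at −3.32 and the haem carrier Hpx at 1.38. Matrix genes fell in 9 of 26 cases (9 adjusted over the list alone, adjusted p = 0.628 with an estimated correlation), with Col1a2 at −1.06. Endothelial markers fell in 5 of 17 cases (7 adjusted over the list alone, median −0.26, adjusted p = 0.418 with an estimated correlation) and stellate cell markers in 4 of 15 (4 adjusted over the list alone, median −0.30, adjusted p = 0.383 with an estimated correlation). Monocyte and infiltrating macrophage markers were not called as a list, with 0 of 17 up and 4 down (4 down adjusted over the list alone), among them Lyz2 at −0.74. Cholangiocyte markers were not called either, with 3 of 11 up (3 adjusted over the list alone), among them Sox9 at 2.02.

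At day 13, 3377 genes were called, with 5123 at an unadjusted p under 0.05, 3775 called by DESeq2 and 2718 by limma-voom. The count was 2014 when the 6 day 13 libraries were fitted alone. The order of the counts at the 2 days thus turned with the samples in the fit. It also turned by limma-voom on all 12 libraries, which called 2749 at day 9. For ribosomal proteins the order turned as well, since the day 9 libraries alone gave 39 of 47 and 30 of 34 up. The numbers called at the 2 days are therefore no measure of which day had the larger effect. The fit on the day 13 libraries alone called 36 of 47 and 22 of 34 ribosomal proteins up, 7 of 74 mitochondrial ribosomal proteins up, 6 of 19 heat shock proteins up, and 1 of 6 erythroid, 3 of 17 endothelial and 2 of 15 stellate cell markers and 10 of 37 interferon-stimulated genes down. The 9 other splits of the day 13 libraries, each with 1 siRNA library exchanged for 1 control library, called at most 8 genes. Camera called 10 to 25 lists in them and 27 of the 49 lists in the real split. Its call ended without at least 1 library for 7 lists, among them matrix genes without control replicate 2 (adjusted p 0.147), endothelium without siRNA replicate 2 (0.0596), mitochondrial ribosomal proteins without control replicate 3 or siRNA replicate 1 (0.0864 to 0.292), major urinary proteins without control replicate 3 or siRNA replicate 1 or 3 (0.0585 to 0.766), and stellate cells without any day 9 siRNA replicate, control replicate 3 of day 9, or control or siRNA replicate 2 of day 13 (0.0552 to 0.104). It also ended for fatty acid oxidation without any control but day 13 replicate 3, day 9 siRNA replicate 3 or day 13 siRNA replicate 2 (0.0678 to 0.146), and for heat shock proteins without any library but day 13 control replicate 3 and siRNA replicates 2 and 3 (0.0585 to 0.108).

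**Figure D2:**
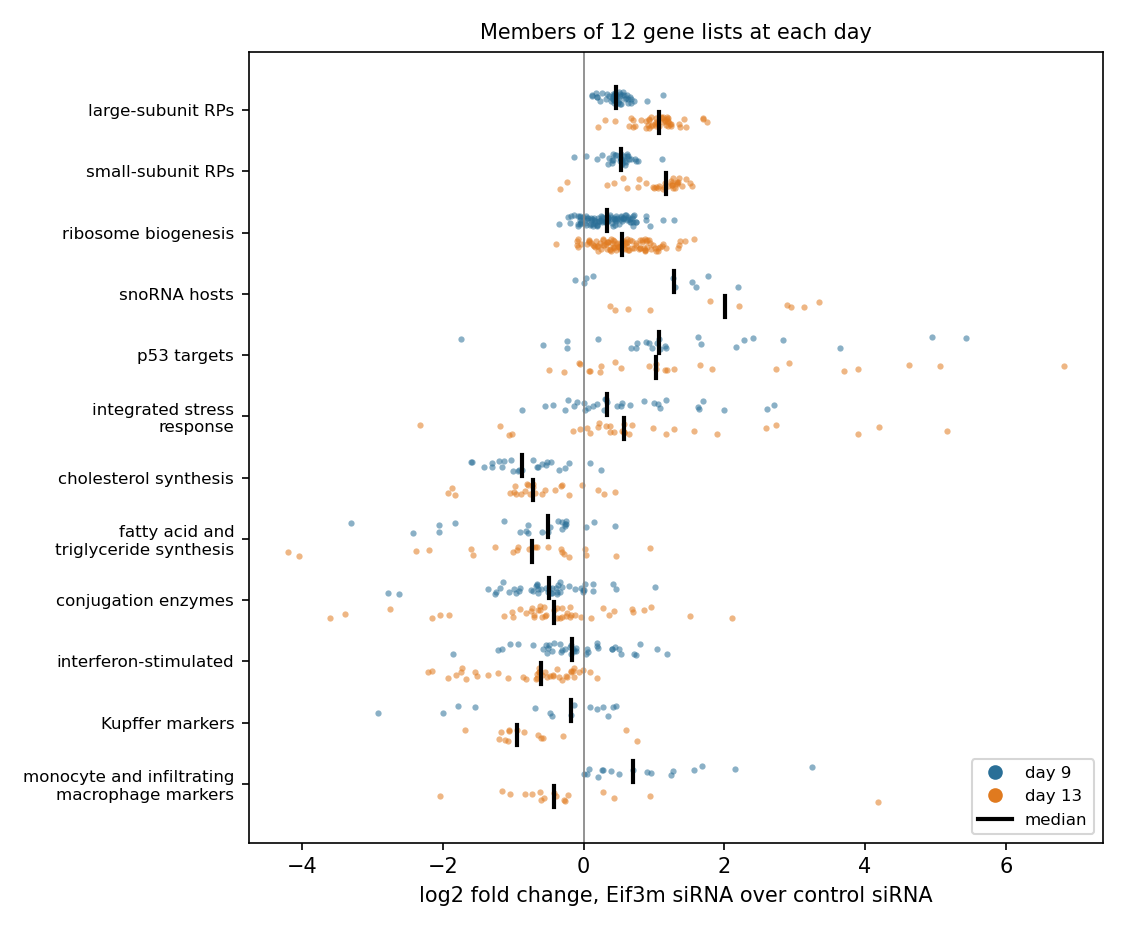
Log2 fold change of Eif3m siRNA over control siRNA (horizontal axis) for the tested members of 12 gene lists (vertical axis), at day 9 and day 13, with each point a gene and each black bar the list median. The ribosomal protein (RP) medians lie at 0.46 and 0.53 at day 9 and at 1.08 and 1.18 at day 13, and Kupffer cell markers have a median of −0.95 at day 13.

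Across the days, 504 genes were higher at both and 588 lower at both, where independent lists of these sizes would share 108 and 106. Cdkn1a, Ifrd1, Arhgef2, Gas5 and Atf5 were among the genes that rose at both days, and Gstt3, Cyp2b10, Insig1, Fasn, Clec4f and Eif3m among those that fell at both. Opposite directions were called for 47 genes, where independent lists would give 217. Of the 1821 genes called at day 9, 86.9% had the same sign at day 13, and over all genes, which are not independent replicates, the log2 fold changes of the days had a Pearson r of 0.393 and a Spearman rho of 0.402. The total of 1092 genes called alike was 582, 629 and 719 without day 9 siRNA replicate 2, day 9 control replicate 3 and day 9 siRNA replicate 1.

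The difference between the days was tested directly, as the day 13 effect minus the day 9 effect. Gadd45a, a growth arrest gene, rose 2.21 log2 units more at day 13 (adjusted p = 0.000376), going from 6.36 ± 0.792 to 71.3 ± 5.20 CPM there and from 9.48 ± 1.35 to 22.9 ± 2.44 CPM at day 9 (SD, n = 3). Trib3 rose 3.47 log2 units more at day 13. Lyz2 had a difference of −2.00 (adjusted p = 0.000664), with 66.4 ± 8.30 CPM in the day 13 siRNA livers (SD, n = 3), and Dnajb9 one of −1.92 (adjusted p = 0.000664). The controls of the days differed too: Lyz2 stood at 42.0 CPM at day 9 and 111 CPM at day 13, Dnajb9 at 45.1 CPM at day 9 and 128 CPM at day 13, and Trib3 at 10.4 and 2.12 CPM. In all, 128 genes had a higher and 236 a lower effect at day 13, so that 35.2% were higher.

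Among ribosomal proteins the difference passed the threshold for 4 of 47 large-subunit genes (22 adjusted over the list alone) and 1 of 34 small-subunit genes (22 adjusted over the list alone), with medians of 0.60 and 0.64. The medians were 0.38 and 0.42 without day 13 control replicate 3, in which ribosomal protein genes and their named pseudogenes made up 0.996% of the counts against 1.40% and 1.52% in the other day 13 controls. With an estimated correlation adjusted p = 0.332 for the large subunit and adjusted p = 0.367 for the small subunit. Monocyte and infiltrating macrophage markers had a lower effect at day 13 in 5 of 17 cases (9 adjusted over the list alone, median −1.01, adjusted p = 0.0742 with an estimated correlation), among them Lyz2, Itgax and Ccr2. Matrix genes had one in 6 of 26 cases (14 adjusted over the list alone, median −0.68, adjusted p = 0.251 with an estimated correlation), among them Col1a2. Female-biased genes had one in 6 of 20 cases (10 down and 3 up adjusted over the list alone, median −0.49, adjusted p = 0.251 with an estimated correlation), among them A1bg with a difference of −4.99. Interferon-stimulated genes had one in 5 of 40 cases (13 adjusted over the list alone, median −0.57, adjusted p = 0.251 with an estimated correlation), among them Usp18. Upper-quartile scaling gave 86 higher and 290 lower effects, or 22.9% higher. The count of 364 was 997 by DESeq2, and it was 172, 187 and 207 without day 9 control replicates 1, 2 and 3, 130 and 164 without day 9 siRNA replicates 1 and 3, 222 without day 13 control replicate 1 and 155 without day 13 siRNA replicate 3. Day, library set and depth coincide, so a difference between the days cannot be assigned to time.

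**Figure D3:**
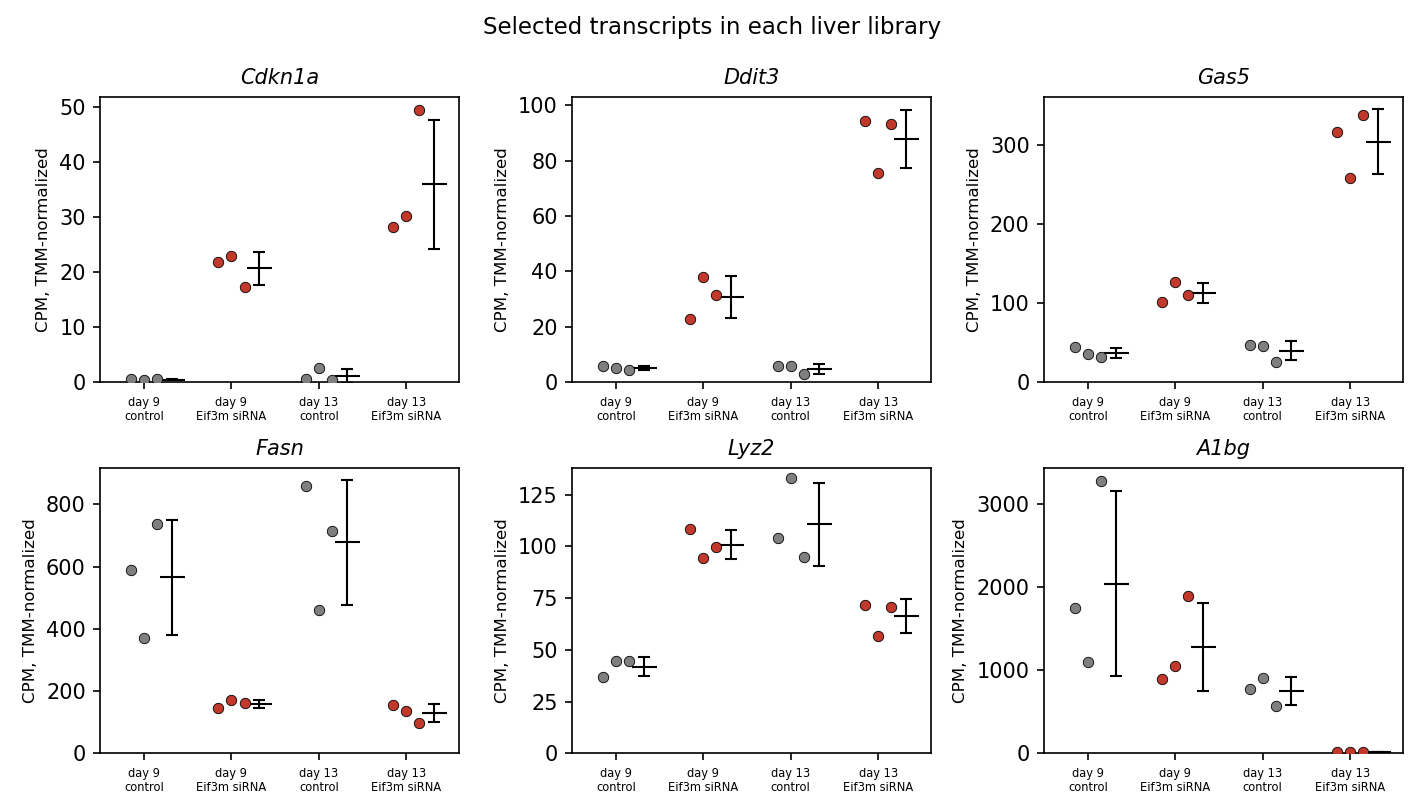
TMM-normalized CPM (vertical axes) of Cdkn1a, Ddit3, Gas5, Fasn, Lyz2 and A1bg in each library, by group (horizontal axes), with points for single libraries (3 per group) and bars for the mean ± SD. Lyz2 is higher in the siRNA livers at day 9 and lower at day 13, and A1bg falls from 748 to 14.7 CPM at day 13.

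Some of these values carry the uncertainty of shared reads. Exons of Ddit3 overlap those of Mars, Zfas1 those of Znfx1, Atf5 those of Il4i1 and Nup62, Ifrd1 those of Gm7008, Nop56 those of Idh3b, Csf1r those of Hmgxb3, Gadd45a those of E230016M11Rik and Glul those of Teddm2. Ribosomal proteins have many processed pseudogenes, and the Mup, Gstt, Cyp2 and alpha-globin genes have close copies.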

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

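The tests of transcript length, of haemoglobin, of blood-free Kupffer cell markers, of the share of non-hepatocyte RNA, of Y-linked counts and of near-identical genes, and the use of all 17 myeloid markers in the thinning test, were chosen only after the result was seen, and the counts of other splits had been seen before their bounds were written down. What set the following results apart was the test of the difference between the days, the day 13 effect minus the day 9 effect on the log2 scale.

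Among stress response and immediate early genes the difference was 6.2 for Egr1, 3.47 for Trib3, 2.28 for Gdf15, 2.21 for Gadd45a, 2.04 for Hspb1, 1.60 for Ddit3, 1.51 for Junb and 0.91 for Plk2. It was −3.37 for Hspa1a, −2.78 for Hspa1b, −1.92 for Dnajb9, −1.23 for Bag3 and −0.84 for Herpud1. Egr1 stood at 3.90 at day 13, so its difference also holds an effect below 0 at day 9. Hspa1a and Hspa1b stood at 1.60 and 1.37 at day 9, so their differences hold effects below 0 at day 13. In the translation machinery the difference was 0.68 for Rpl9, 0.74 for Rpl4, 0.78 for Rplp0, 0.79 for Rps4x, 0.89 for Eif3i, 0.94 for Eef1b2 and 0.66 for Npm1. Among hosts of small nucleolar RNAs it was 1.57 for Zfas1, 1.34 for Gas5 and 1.83 for Snhg1.

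Among myeloid and other immune genes the difference was −3.72 for Itgax, −2.00 for Lyz2, −1.64 for Ccr2, −1.33 for Itgb2, −1.39 for Csf1r, −1.53 for Adgre1, −1.65 for Itgal and −1.44 for Ctss. Interferon-related genes had −2.01 for Cxcl9, −1.99 for Gbp9, −1.41 for Usp18, −1.22 for Igtp and −1.09 for Iigp1. Acute phase genes had −3.19 for Orm2, −2.22 for Lcn2 and −0.69 for Crp. Endothelial and matrix genes had −2.07 for Lyve1, −0.79 for Vwf, −1.41 for Vcam1, −1.65 for Col1a2 and −0.94 for Tgfbi, and Sox9 had 1.71. Among genes that differ between the sexes it was −4.99 for A1bg, −2.36 for Sult3a1, −1.96 for Fmo2, −1.88 for Slc22a26, 2.36 for Mup21, 2.35 for Hsd3b5 and 1.53 for C6. Metabolic and other genes had −2.94 for Slc25a25, −2.64 for G6pc, −2.56 for Per1, −0.66 for Dgat2, 1.95 for Gjc3, 1.87 for Cyp2u1, 0.84 for Gpt2, 1.24 for B4gat1, 2.02 for Ethe1 and 1.69 for Slc43a1.

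By camera with the preset correlation 23 lists differed between the days, and none of them with an estimated correlation. For this difference the main gene test called 0 of 7 erythroid, 0 of 31 cell cycle, 0 of 15 stellate cell and 0 of 75 mitochondrial ribosomal protein genes. DESeq2 called 0, 4, 1 and 0 of them. Over the list alone, 1 cell cycle gene passed upward and 4 downward. Ribosome biogenesis factors had 2 of 95 called by the main test and other translation factors 1 of 32 (8 adjusted over the list alone). Upward medians were 0.70 for small nucleolar RNA hosts (1.31 with a mean of at least 5 CPM), 0.64 and 0.60 for small-subunit and large-subunit ribosomal proteins, 0.54 for major urinary proteins, 0.37 for other eIF3 subunits, 0.37 for male-biased genes, 0.33 for immediate early genes, 0.26 for other translation factors, 0.25 for ribosome biogenesis, 0.24 for amino acid catabolism, 0.22 for mitochondrial ribosomal proteins and 0.17 for the integrated stress response. Downward medians were −1.08 for erythroid cells, −1.01 for infiltrating monocytes and macrophages, −1.005 for the cell cycle (0.049 with a mean of at least 5 CPM), −0.73 for Kupffer cells, −0.68 for matrix genes, −0.57 for interferon-stimulated genes, −0.49 for female-biased genes, −0.47 for inflammatory chemokines (−0.26 with that filter, where the call ended), −0.39 for stellate cells, −0.36 for the acute phase and −0.34 for endothelium. Calls ended for mitochondrial ribosomal proteins (adjusted p 0.113) and the integrated stress response (0.135) without day 13 control replicate 3, for immediate early genes (0.0558 to 0.0598) without control replicate 3 of either day, and for erythroid cells (0.0958 to 0.115) without day 13 control or siRNA replicate 2. They ended for major urinary proteins (0.0611 to 0.860) without day 9 control replicate 2, day 13 control replicate 3 or day 13 siRNA replicate 1 or 3, and for chemokines (0.0568 to 0.117) without day 9 control replicate 3, day 9 siRNA replicate 1, day 13 control replicate 1 or day 13 siRNA replicate 2, and also with a replicate block and with day 9 thinned. With the block it ended for erythroid cells as well. Without day 13 control replicate 3 the medians were 0.38 and 0.42 for large-subunit and small-subunit ribosomal proteins, 0.46 for small nucleolar RNA hosts, 0.11 for the integrated stress response, 0.10 for mitochondrial ribosomal proteins and 0.081 for major urinary proteins. Without day 9 siRNA replicate 1 they were −0.56 for the cell cycle, 0.55 for immediate early genes and 0.10 for the integrated stress response, and without day 9 control replicate 2 −0.65 for the cell cycle and 0.33 for major urinary proteins. For female-biased genes they were −0.75 and −0.78 without day 9 control replicate 3 and day 13 siRNA replicate 3, and for small nucleolar RNA hosts 1.14 without day 13 control replicate 1. Without day 13 control replicate 2 they were −0.56 for erythroid cells and 0.61 for male-biased genes, and without day 13 siRNA replicate 2 0.61 for male-biased genes and 0.34 for mitochondrial ribosomal proteins. Without day 13 siRNA replicate 1 they were 0.13 for mitochondrial ribosomal proteins and 0.29 for major urinary proteins, and without day 13 siRNA replicate 3 0.34 for the latter.

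Calls were also counted in other splits of the libraries. At day 9 the real split called 1821 genes and the highest of the others 1, and 1 of 10 splits reached the real count; for lists the values were 24 and 28, with 3 of 10. At day 13 they were 3377 and 8 genes, with 1 of 10, and 27 and 25 lists, with 1 of 10. With 10 splits the share cannot go under 0.05. The other splits of a day each exchanged 1 siRNA library for 1 control library and keep part of the siRNA effect. They therefore do not show how many genes or lists would be called without an effect. For genes called alike at both days, 1 of 100 splits reached the real 1092, the highest other being 0 by edgeR, and for genes that differed between the days 1 of 100 reached 364, the highest other being 6. For lists that differed between the days, 9 of 100 splits gave as many as the real 23, with up to 26. These splits mix siRNA with control libraries, so they test no effect at either day and say nothing about chance in the overlap or in the difference.

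The first pattern weighed is the rise of ribosomal protein transcripts at day 13, with a median of 1.12 over 81 genes (SE 0.0423). The SEs of medians here and under the hypotheses given last come from redrawing the genes of each set. They treat genes as independent and hold no spread between livers, so they understate the uncertainty for genes that move together. A bias toward short transcripts is argued against by 390 other genes matched on length, GC content and CPM, whose median was −0.053 (SE 0.0246). The match was incomplete, with a median transcript length of 927 against 771 for ribosomal protein genes and a median CPM of 91.6 against 141. A shift of composition that moves all genes alike would leave ribosomal protein genes level with the rest. With the 10 most abundant genes taken out their median lay 1.12 above that of all genes, which argues against such a shift. A scaling factor shared by all genes cancels from this difference, so the removal adds no separate evidence. Reads shared with pseudogenes are argued against by the summed counts of the genes and 56 named pseudogenes, which were 1.19 higher, with all 3 siRNA libraries above the controls. Loss of eIF3m remains as a biological hypothesis for the rise within day 13, and for its larger size than at day 9, day and library set cannot be told apart, although thinning day 9 left that difference at 0.616 against 0.618.

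The second pattern is in macrophage markers, with infiltrating monocyte and macrophage markers at a median of 0.70 at day 9 (0.42 without siRNA replicate 1) and Kupffer cell markers at −0.95 at day 13. With all libraries in the fit, haemoglobin genes at day 9 had a mean of −0.44, more than 2 SE below the myeloid median of 0.70. The SE used, 0.481, was the mean of the SEs of the single genes. Without siRNA replicate 1 the myeloid median was 0.42, and the haemoglobin mean was not computed for that set of libraries. Whether the gap holds without that library is therefore not known, and residual blood stays open at day 9. At day 13 haemoglobin genes stood at −1.57. Residual blood is argued against there as the whole cause by the 11 Kupffer cell markers of the list that blood cells lack, at −0.95 (SE 0.190). With Fcna, which is not in that list, their median was −1.003. A lower share of all non-hepatocyte RNA at day 13 is argued against as the whole cause by cholangiocyte markers, whose median lay 1.11 (SE 0.288) above that of Kupffer cells. Stellate cell and endothelial markers fell less than Kupffer cell markers, with medians of −0.30 and −0.26, and erythroid markers fell too. A lower share as part of the cause therefore stays open. Depth is argued against as the whole cause of the myeloid difference between the days, which over the 17 markers was −1.27 (SE 0.323) with day 9 thinned and −1.01 before, and over the 11 that a filter on the thinned counts left −1.11 and −1.13. Day and library set cannot be told apart for that difference, and a change in macrophage numbers or in their expression was not tested.

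The third pattern is the lower level of female-biased genes at day 13, with a list median of −0.69. A male liver among the siRNA libraries is argued against by 0 counts over 4 Y-linked genes in the day 13 siRNA libraries, with 3 counts in all 12 libraries. Reads shared between near-identical genes are argued against as the whole cause by the 7 members with no such copy, of which 4 were called lower and none higher, where the share of all genes would give 0.763 lower, although their median of −2.06 had an SE of 1.60. They stay open for the 13 members with copies, since the counts summed over their families of 54 genes changed by −0.35 and those members held 27.4% of them. A change in growth hormone signalling, on which these genes depend, was not tested.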

How the results depend on the processing

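The thinning of day 9 counts was chosen after seeing the data. Of 289 results for named genes, none reversed under any alternative, 246 lost no call under any, 43 lost one in at least 1 and 5 gained one in at least 1. Results that an alternative did not test count here as not lost. With a mean of at least 5 CPM 263 of the 289 were compared, and the fits of each day alone gave no difference between the days. Eif3m kept its direction and call under every alternative at both days. Of 74 list calls, 69 were lost in at least 1 alternative, all of these with an estimated correlation, which left 1 list at day 9, 4 at day 13 and 0 between the days. The test fry, which makes no comparison with other genes, gave 15 lists between the days. The cell cycle list reversed with a mean of at least 5 CPM, to −0.12 at day 9 and 0.049 between the days, where fewer genes were tested. With that filter calls also ended for Kupffer cells at day 9 and chemokines between the days. With a replicate block they ended for heat shock proteins at day 13 and for chemokines and erythroid cells between the days. With day 9 thinned they ended for the cell cycle at day 9, for heat shock proteins, fatty acid oxidation and stellate cells at day 13 and for chemokines between the days.

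At day 9 the count of 1821 genes became 2749 by limma-voom, 3412 on the day's own 6 libraries and 1186 with counts thinned to the day 13 depth. Thinned and fitted on its own 6 libraries, day 9 gave 2352. At day 13 the count of 3377 became 2014 on its own 6 libraries. Fitting the days apart gives each its own spread, and the median SD was lower at day 9. Between the days the count of 364 became 997 by DESeq2 and 117 with a replicate block; the cause was not tested. The block takes up residual degrees of freedom, and libraries with the same number were not more alike, so they were not paired.

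Without 1 library the counts were 884 to 2250 at day 9, 2299 to 3288 at day 13, 130 to 508 between the days and 582 to 1267 at both days. Lists numbered 22 to 25, 24 to 30 and 21 to 27. The scalings moved the median of all genes by less than 0.1. The thinned counts show that depth adds calls at day 9. In simulated data only 14.9% of genes changed 1.5-fold were recovered at day 9 and 22.4% at day 13, so small changes were often missed there at either depth. The simulated spread was the same at both days, so these rates may differ in the real data.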

Other observations

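For the hypotheses given last, the leaving out of 2 transcripts from the list with a 5 prime TOP motif was chosen only after the result was seen. Lists with no call at either day held some called genes. Among secreted hepatocyte proteins Apoc3 stood at −0.97 at day 9 and −1.45 at day 13 and Apoa2 at −1.11 and −0.99. Of the 30 genes of that list, 4 fell at day 9 (6 adjusted over the list alone), and 6 fell and 3 rose at day 13 (9 and 3 adjusted over the list alone). In nucleotide synthesis, 2 of 27 genes rose and 3 fell at day 9 (4 and 3 adjusted over the list alone), and 11 rose and 5 fell at day 13 (11 and 5 adjusted over the list alone), with Ctps, of CTP synthesis, at 1.11 and 1.41 and Adssl1 at −1.07 and −0.99. Among clock genes 1 of 18 fell at day 9 (1 adjusted over the list alone) and 3 at day 13 (3 adjusted over the list alone). Periportal markers had 2 of 13 up and 3 down at day 9 (2 and 4 adjusted over the list alone), and 2 up and 1 down at day 13 (2 and 1 adjusted over the list alone), with Hsd17b13 at 0.52 at day 13. Among fetal liver markers 1 of 10 rose at each day (1 adjusted over the list alone), Lpl, at 0.89 and 1.03, and the day 9 call of Lpl was lost without control replicate 3 or siRNA replicate 1 or 2 (adjusted p up to 0.0707).

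Mitochondrially encoded transcripts had 0 of 13 called at either day by edgeR or limma-voom, 0 and 1 by DESeq2, and 0 and 1 at an unadjusted p under 0.05, while edgeR on the day 9 libraries alone called 1 lower. Exocrine pancreas markers had 1 of 3 up at day 9 (1 adjusted over the list alone), Cela2a at 1.41, and 0 at day 13 by edgeR, with 1 by DESeq2 and 1 at an unadjusted p under 0.05. Adipose and muscle markers had 0 of 2 called at either day by edgeR, DESeq2 or limma-voom, and 0 at an unadjusted p under 0.05. Median, mean and test differed in sign at day 9 for the unfolded protein response (0.02, −0.06 and down), the acute phase (0.02, −0.10 and down), glucose metabolism (−0.14, 0.06 and down), periportal markers (−0.13, 0.13 and down), cholangiocytes (−0.05, −0.02 and up) and exocrine pancreas (−0.25, −0.10 and up). They also differed at day 13 for mitochondrially encoded transcripts (−0.13, −0.09 and up), chemokines (−0.03, 0.11 and up), the proteasome (−0.01, 0.03 and up), amino acid catabolism (−0.01, 0.01 and down) and exocrine pancreas (0.28, 0.00 and down).

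Because Gas5, Zfas1 and ribosomal protein transcripts share a 5 prime TOP motif, a rise common to such transcripts may account for their rising together. Among 12 other transcripts known to carry the motif, 6 rose at day 9 (6 up and 1 down adjusted over the list alone) and 9 at day 13 (9 adjusted over the list alone), with medians of 0.30 (SE 0.125) and 0.67 (SE 0.140), as the hypothesis required at both days. Eef1b2 and Npm1 had been left out because the fixed lists hold them, and with all 14 the medians were 0.37 and 0.73. No set of transcripts without the motif was compared. Ribosome biogenesis factors, a list not chosen for the motif, had medians of 0.33 at day 9 and 0.55 at day 13. The rise of the 12 transcripts therefore does not single out the motif. Whether translation, stability or transcription of the transcripts with the motif changed was not analysed here.

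Gas5, Ddit3 and Gadd45a are also known targets of nonsense-mediated decay, so weaker decay could raise them. Transcripts of 10 decay factors, which that pathway is known to hold down, had medians of −0.028 (SE 0.0945) at day 9 and −0.029 (SE 0.0935) at day 13. Of the 10, 1 fell at day 9 (0 adjusted over the list alone) and 1, Upf3a at 0.86, rose at day 13 (1 adjusted over the list alone). The bound set beforehand, a median at or under 0 or within 2 SE of it, was wrong, since both medians lay under 0 by less than 1 SE and a small rise lies within 2 SE. Weaker decay therefore stays open.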
